A study of Mus musculus with 2 samples.

How the data were processed

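H3K27me3 chromatin immunoprecipitation and sequencing was performed on kidneys of embryonic day 14.5 mice of the strain labelled B6NTac;B6NCrl/Lap, with fragments of 300 to 500 bp, per the labels. The 2 samples are biological replicates of 1 group, numbered in the labels. Both were pooled from male and female embryos, in shares not given in the sources used here. Per the deposited descriptions, each replicate's peaks were called from its alignments to mm10 with the same pair of control files, the pooled peaks from both replicates together, and the replicated list from the replicates' lists and the pooled list. The aligner, the peak caller, its threshold and the rule for calling a peak replicated are not given in the sources used here.

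Each peak of the replicated list has the coordinates of a peak in the pooled list. Each deposited peak has a signal value, which the authors' peak caller gave and whose exact definition is not stated. The design had called this value a fold enrichment; it is reported as a signal value and used only to describe and rank peaks. The deposited lists also give a −log10 p-value and a −log10 q-value per peak. Read counts were not used here, so depth per sample is unknown and the precision of a peak call rests on the agreement of the replicates. Intervals on shares of genes are exact binomial intervals at 95% and cover counting error only.

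Coordinates are mm10, the build GRCm38. All peaks lay inside the GRCm38 lengths of 20 chromosomes. Genes came from GENCODE release M21. Of 21938 protein-coding genes, 183 on Y and 27 sharing a symbol were left out, leaving 21728. No list had a peak on Y. A promoter was the gene's annotated 5' end ± 1 kb and was marked when a replicated peak overlapped it by at least 1 bp. Coverage is the share of bases within 5 kb of the start that replicated peaks cover. At most of the genes named below, the peaks of replicate 1 alone covered less. A promoter was CpG-rich when the start ± 0.5 kb had an observed-to-expected CpG ratio of at least 0.6 and a GC share of at least 0.5. Broad domains were peaks merged across gaps of at most 3 kb and at least 10 kb long.

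Peak positions were compared with 200 circular rotations of the peaks within each chromosome. Gene groups were tested with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment over 36 lists, with all other tested genes as the background. The Hox comparisons used an exact permutation test or 100000 permutations. These tests treat genes or regions as units within 1 tissue, so their p-values do not measure variation between embryos. The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took 19 panel genes, up to 4 genes in each of the 10 longest domains, the 2 most covered marked members of each list (up to 8 in the kidney lineage lists), and the 10 genes, 1 per domain, with the highest signal value at the promoter.

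Alternatives were a −log10 q of at least 5, an overlap of at least 50% of the shorter peak, 25% of the promoter covered, a promoter window of 2.5 kb, the start of any transcript, the pooled peaks, each replicate's list alone, CpG-rich promoters only, a CpG ratio of 0.75, rotation of the marks along the gene order (10000 times), equal peak numbers, a Hox window of 1 kb, and merge distances of 1 and 10 kb. Further alternatives, the replicated peaks overlapping both replicates and autosomes alone, were chosen after seeing the data. The functions were tested on simulated data. For the gene list comparison on 21728 genes, 87.5% of lists raised to a marked share of 50% were called, and 2.14% of unchanged lists were. The simulation marked genes independently, whereas real neighbours share peaks, so these rates need not hold for the data. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.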

Results

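Trimethylation of histone H3 at lysine 27 (H3K27me3), a mark deposited by Polycomb repressive complex 2 and associated with silenced genes, was profiled by chromatin immunoprecipitation and sequencing in whole mouse kidney at embryonic day 14.5. At this stage branching ureteric epithelium, nephron progenitors, forming nephrons, stroma, vessels and blood cells lie side by side. The samples form 1 group of 2 biological replicates, each prepared from kidneys of pooled male and female embryos. The question addressed is where the mark lies in this tissue, and how far the replicates give the same answer. No second condition exists, so all comparisons are between replicates, gene groups or regions within the group. The files used here hold peaks and no read counts, so sequencing depth is unknown and no interval for depth is given.

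The authors' replicated list held 22708 peaks covering 18.9 Mb, or 0.717% of the genome, with a median width of 474 bp. Its largest deposited signal values at promoters were at Nkx1-1 (signal value 13.3), a homeobox gene, and Adra2c (13.1), which encodes an adrenergic receptor. Neurog3, the endocrine pancreas regulator, and Bcan, a brain proteoglycan gene, both reached 12.6. Egr4, Olig1, Irx4, Skor2, Bhlhe23 and Cilp2 completed the 10 highest, with values from 11.6 to 12.4. Replicate 1 alone gave 54867 peaks over 20.1 Mb, replicate 2 alone gave 65849 over 29.2 Mb, and the pooled data gave 45344 over 24.6 Mb. Of the replicated peaks, 17960 (79.1%) overlapped a peak of both replicates, 3595 overlapped replicate 2 only, 1111 overlapped replicate 1 only and 42 overlapped neither. The share found in both replicates was 63.8% in the lowest of 4 groups ranked by signal value and 98.1% in the highest. Because the replicated list was made from the replicates' lists, such overlap is partly built in.

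The replicates' own peaks shared 29.3% of all bases covered in either list. Randomly rotating the replicate 2 peaks along each chromosome gave at most 0.942% in 200 rotations (one-sided permutation p = 0.00498, the smallest these rotations can give). In replicate 1, 25858 peaks (47.1%) overlapped a replicate 2 peak, and in replicate 2, 20711 peaks (31.5%) overlapped a replicate 1 peak. Across the 17960 replicated peaks found in both, the signal values had a Spearman correlation of 0.507 and a Pearson correlation of 0.585 on the log2 scale. These correlations run across peaks, which are not independent replicates.

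Promoters of 2986 of 21728 protein-coding genes (13.7%) overlapped a replicated peak within 1 kb of the gene's annotated 5' end. Such promoters are called marked. Rotated peaks reached 381 promoters on average and 465 at most, a 7.84-fold difference from the mean (one-sided permutation p = 0.00498, the smallest possible). Of the marked promoters, 2782 (93.2%) were also called in each replicate's own list. The replicated list was made from the replicates' lists, so this share is partly built in. Replicate 1 called 4016 promoters and replicate 2 called 3878, with 3025 in common, and Cohen's kappa was 0.715 ± 0.006 (SE). This SE treats genes as independent and does not measure variation between replicates. Among the panel genes chosen for the tissue, the housekeeping genes Actb and Gapdh, the endothelial gene Pecam1 and the proximal tubule phosphate transporter gene Slc34a1 were unmarked. Cdkn2a, the cell cycle inhibitor locus, was marked, with 91.5% of the 5 kb on either side of its start covered by replicated peaks. With a −log10 q of at least 5 required, 1983 promoters were marked.

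CpG-rich promoters were marked more often than CpG-poor promoters. The mark was present at 1682 of 9722 CpG-rich promoters (17.3%) and at 1304 of 12006 others (10.9%), an odds ratio of 1.72 (two-sided Fisher's exact test, p = 1.66e-42). This difference depended on the definition of CpG-rich. When an observed-to-expected CpG ratio of at least 0.75 replaced 0.6, the odds ratio was 1.00 (Fisher's exact test, p = 1.0).

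Promoters of developmental transcription factor families were marked more often than those of other genes. All 9 Pax genes, all 12 LIM homeobox genes and all 14 NK homeobox genes had marked promoters, as did 13 of 19 Sox, 25 of 44 Fox, 12 of 17 T-box, 11 of 16 Irx, Eya and SIX-class, and 5 of 6 Gata genes. Examples with nearly complete coverage of the 5 kb on either side of the start by replicated peaks were Pax9 (98.0%), Lhx5 (96.9%), Nkx6-2 (97.5%), Sox1 (96.8%), Foxe1 (99.0%), Gata2 (99.0%) and the mesoderm gene T (98.8%). In replicate 1 alone their coverage ranged from 78.85% (Nkx6-2) to 87.03% (Lhx5), and in replicate 2 alone from 93.7% (Sox1) to 96.9% (Foxe1). Secreted signals were also marked, at 16 of 19 Wnt, 13 of 22 Fgf and 12 of 21 Bmp and Gdf genes. Wnt10a reached 98.3% coverage, Gdf7 reached 88.4% and Fgf8 reached 72.9%. These examples are the most covered members, and medians over all members ranged from 26.4% (Fox) to 91.8% (Pax) among these transcription factor families, and were 53.0% for Wnt, 18.6% for Fgf and 8.27% for Bmp and Gdf genes. Each of these 11 families passed Fisher's exact test against all other genes, with Benjamini-Hochberg adjusted p from 7.51e-12 for NK homeobox genes to 0.000407 for Gata genes over 36 lists. The Hox genes, the remaining family, are described separately.

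**Figure D1:**
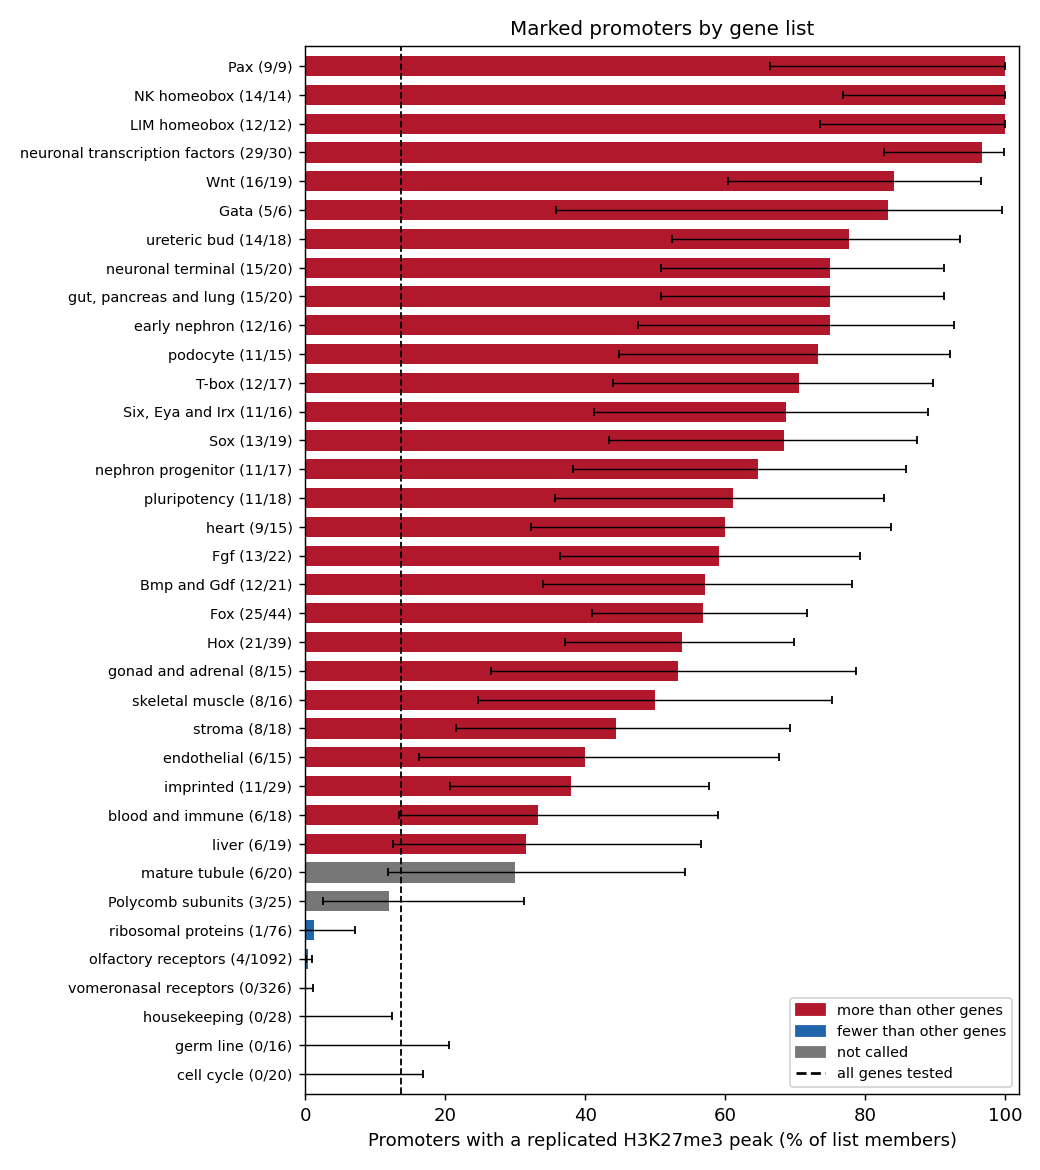
Share of promoters with a replicated H3K27me3 peak in each of 36 gene lists, in percent of list members on the horizontal axis. Bars are shares, lines are exact 95% binomial intervals, and the dashed line is the share of all genes tested, 13.7%. Pax, NK homeobox and LIM homeobox genes reach 100%, while 4 of 1092 olfactory receptor genes are marked.

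Genes that define the lineages of the developing kidney itself were marked more often than other genes. Marked promoters were found for 11 of 17 nephron progenitor genes (64.7%, exact 95% interval 38.3 to 85.8%), 14 of 18 ureteric bud genes (77.8%, 52.4 to 93.6%), 8 of 18 stromal genes (44.4%, 21.5 to 69.2%) and 12 of 16 early nephron genes (75%, 47.6 to 92.7%). Their adjusted p by Fisher's exact test were 3.41e-06, 5.33e-09, 0.00196 and 1.31e-07. In the progenitor list, coverage of the 5 kb on either side of the start was 79.3% at Six2, which maintains progenitor self-renewal, 59.5% at Pax2 and 24.0% at Wt1. It was 25.1% at Gdnf, which encodes the signal for ureteric budding, and 18.6% at Osr1. In the ureteric list, coverage was 97.6% at Tfap2a, 83.3% at Gata3, 57.4% at Wnt9b, 54.5% at Wnt11 and 45.8% at Ret, the Gdnf receptor gene. The stromal regulator Foxd1 had 65.0% coverage, against 10.9% at the collagen gene Col1a1 and 8.70% at Aldh1a2, which makes retinoic acid. Among early nephron genes, Irx2 (96.8%), Lhx1 (91.8%) and Irx1 (90.5%) were the most covered, and Wnt4, the inducer of nephron formation, had 53.0%. All of these genes given with coverage except Col1a1 had less in replicate 1 alone, while replicate 2 alone gave less at some and more at others. Replicates 1 and 2 alone gave 53.75% and 75.73% at Six2, 37.4% and 68.4% at Pax2 and 22.3% and 29.3% at Wt1. They gave 60.97% and 85.37% at Gata3, 69.2% and 86.9% at Lhx1 and 26.9% and 47.3% at Wnt4. Median coverage over all members was 12.6% for nephron progenitor, 32.6% for ureteric bud, 1.37% for stromal and 51.3% for early nephron genes. With a −log10 q of at least 5, Pdgfra, Hoxa11, Aldh1a2, Col1a1, Osr1 and Gdnf were no longer marked, and with 25% of the promoter covered Hoxd11, Hoxa11 and Osr1 were not.

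Markers of more mature or accompanying kidney cell types were marked to differing degrees. Podocyte genes had 11 of 15 marked promoters (adjusted p = 5.84e-07, Fisher's exact test), including Nphs1, the nephrin gene, with 96.2% coverage, and Lmx1b with 88.7%. Endothelial genes had 6 of 15 (Fisher's exact test, adjusted p = 0.0137), with 88.1% coverage at Flt1 and 78.3% at Sox17. Blood and immune genes had 6 of 18 (Fisher's exact test, adjusted p = 0.0331), led by Pax5 and Tal1. This last call was lost when the marks were rotated along the gene order (permutation test, adjusted p = 0.0648), with 25% of the promoter covered (4 of 18 marked) and with a 2.5 kb window (6 of 18). Among CpG-rich promoters the list has 1 member, which was marked, too few for a call (Fisher's exact test, adjusted p = 0.183). Mature tubule genes had 6 of 20 marked promoters and did not pass Fisher's exact test (adjusted p = 0.0511), with Lrp2 (41.2%) and Slc13a3 (26.1%) the most covered. The tubule list passed Fisher's exact test with a −log10 q of at least 5 (adjusted p = 0.0344), with 25% of the promoter covered (0.0159), with a 2.5 kb window (0.0112), among CpG-rich promoters (3 of 4 marked, 0.0233) and with peaks overlapping both replicates (0.0384). The tubule list did not pass in the gene-order rotation (permutation test, adjusted p = 0.110), with pooled peaks, with any transcript's start or in either replicate alone. The genes given with coverage are the most covered of each list, and median coverage over all members was 13.4% for podocyte genes and 0% for endothelial, blood and immune, and mature tubule genes.

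Lists of lineages outside the kidney, except germ line genes (0 of 16 marked), had more marked promoters than other genes. Coverage varied widely between lists. Of 30 neuronal transcription factor genes, 29 were marked (96.7%, exact 95% interval 82.8 to 99.9%, adjusted p = 4.21e-23, Fisher's exact test). Coverage was 100% at Neurog1, 99.2% at Neurod2, 98.7% at Olig2, 97.7% at Pax6 and 77.3% at Neurod1. Neuronal terminal genes had 15 of 20 marked, including Gad2 and Slc32a1 of inhibitory neurons. Skeletal muscle genes had 8 of 16 marked, with 69.5% coverage at the muscle determination gene Myod1. Heart genes had 9 of 15, with 95.9% at Tbx20 and 93.4% at Tbx5, gut, pancreas and lung genes had 15 of 20, with 99.6% at Cdx2, and gonad and adrenal genes had 8 of 15, with 98.8% at Insl3. Liver genes had 6 of 19 (Fisher's exact test, adjusted p = 0.0415), including Foxa2 and Onecut1. The liver call was lost in the gene-order rotation (permutation test, adjusted p = 0.0961), in either replicate alone, with pooled peaks, with a 2.5 kb window and with any transcript's start, although 6 or 7 of 19 were marked in each. Pluripotency genes had 11 of 18, led by Sox2 and Tbx3. Imprinted genes had 11 of 29 (Fisher's exact test, adjusted p = 0.00137), led by Rasgrf1 and Dio3, but among CpG-rich promoters alone, with 5 of 15 marked, the list did not pass (adjusted p = 0.175). Over all members, median coverage was 94.2% for neuronal transcription factor genes, 83.9% for gut, pancreas and lung, 74.3% for heart, 46.2% for neuronal terminal, 15.8% for gonad and adrenal, 15.6% for pluripotency, 4.48% for skeletal muscle, and 0% for liver and imprinted genes.

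A separate set of lists had fewer marked promoters than other genes. Olfactory receptor genes were marked at 4 of 1092 promoters (adjusted p = 2.16e-63, Fisher's exact test) and vomeronasal receptor genes at 0 of 326 (adjusted p = 1.57e-20). The marked receptors were Olfr1416, Olfr222, Olfr63 and Olfr95, of which Olfr1416 and Olfr63 were named after their values were seen. Olfr222 was no longer marked with a −log10 q of at least 5, and Olfr95 was not marked in replicate 1 alone or with 25% of the promoter covered. A CpG-rich promoter was found for 1 vomeronasal gene and no olfactory gene. Ribosomal protein genes were marked at 1 of 76 promoters (Fisher's exact test, adjusted p = 0.000473). That gene was Rpl3, where 1 of 7 annotated start sites, the outermost one used here, had a replicated peak. Housekeeping genes were marked at 0 of 28 (Fisher's exact test, adjusted p = 0.0313). In replicate 1 alone 2 were marked and the call was lost (Fisher's exact test, adjusted p = 0.160). With a −log10 q of at least 5 and with 25% of the promoter covered the count stayed 0 of 28, but fewer other genes were marked and the exact test was not passed (adjusted p = 0.116 and 0.120). The lists of germ line genes (0 of 16), cell cycle genes (0 of 20) and Polycomb subunit genes (3 of 25) did not pass Fisher's exact test, with adjusted p of 0.156, 0.105 and 1.0. Cell cycle genes passed the same exact test with pooled peaks (adjusted p = 0.0411) and in replicate 2 alone (0.0409). Cbx8 and Cbx4, which encode subunits of Polycomb repressive complex 1, had 74.2% and 52.3% coverage, but at Cbx4 0.5% of the promoter itself was covered and the call was lost with 25% required. In total 28 lists had more marked promoters, 4 had fewer and 4 were not called. Lists share members, such as Foxa2 in the Fox, liver and gut lists, so these counts are not independent.

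Among the 39 Hox genes, 21 promoters were marked, and the mark was concentrated at the posterior ends of the clusters. The 6 genes of paralog groups 12 and 13 had a mean coverage of 81.8% ± 22.1 (SD across genes) in the 5 kb on either side of the start, against 10.6% ± 13.5 in the 33 genes of groups 1 to 11 (two-sided exact permutation test, p = 9.2e-07 over 3262623 arrangements). Hoxb13 had 99.0%, Hoxc13 96.1%, Hoxc12 94.8%, Hoxa13 84.0%, Hoxd13 77.3% and Hoxd12 40%. The difference between groups 12 to 13 and groups 1 to 11 was 71.2 percentage points in the replicated list. It was 66.5 points in the replicate 2 list alone and 50.4 points in the replicate 1 list alone. In replicate 1 alone Hoxd13 had 38.1% and Hoxd12 10.5%, against 79.1% and 44.0% in replicate 2 alone. Group 11 genes, active in the metanephros, had 12.9% at Hoxa11, 41.6% at Hoxc11 and 42.5% at Hoxd11. Groups 9 to 11 averaged 17% ± 14.3 in 10 genes and groups 1 to 8 averaged 7.82% ± 12.5 in 23 genes, which did not pass the test (two-sided permutation test, p = 0.0725). That difference passed in the replicate 2 list alone (13.5 percentage points, permutation p = 0.0296), in the replicate 1 list alone (6.76 points, p = 0.0478) and in the pooled list (14.4 points, p = 0.0182), but not with a −log10 q of at least 5 (2.08 points, p = 0.457), within 1 kb of the start (7.59 points, p = 0.401) or with peaks overlapping both replicates (6.77 points, p = 0.141). All 9 Hoxc genes were marked, and 43.1% of that cluster was covered, against 10.5% of Hoxa, 10.1% of Hoxb and 12.1% of Hoxd. At the opposite ends, Hoxa1 (35.2%), Hoxd1 (33.2%) and Hoxb1 (19.4%) were covered while Hoxb2 to Hoxb7 had none. Neighbouring genes share peaks, so genes of a cluster are not independent.

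**Figure D2:**
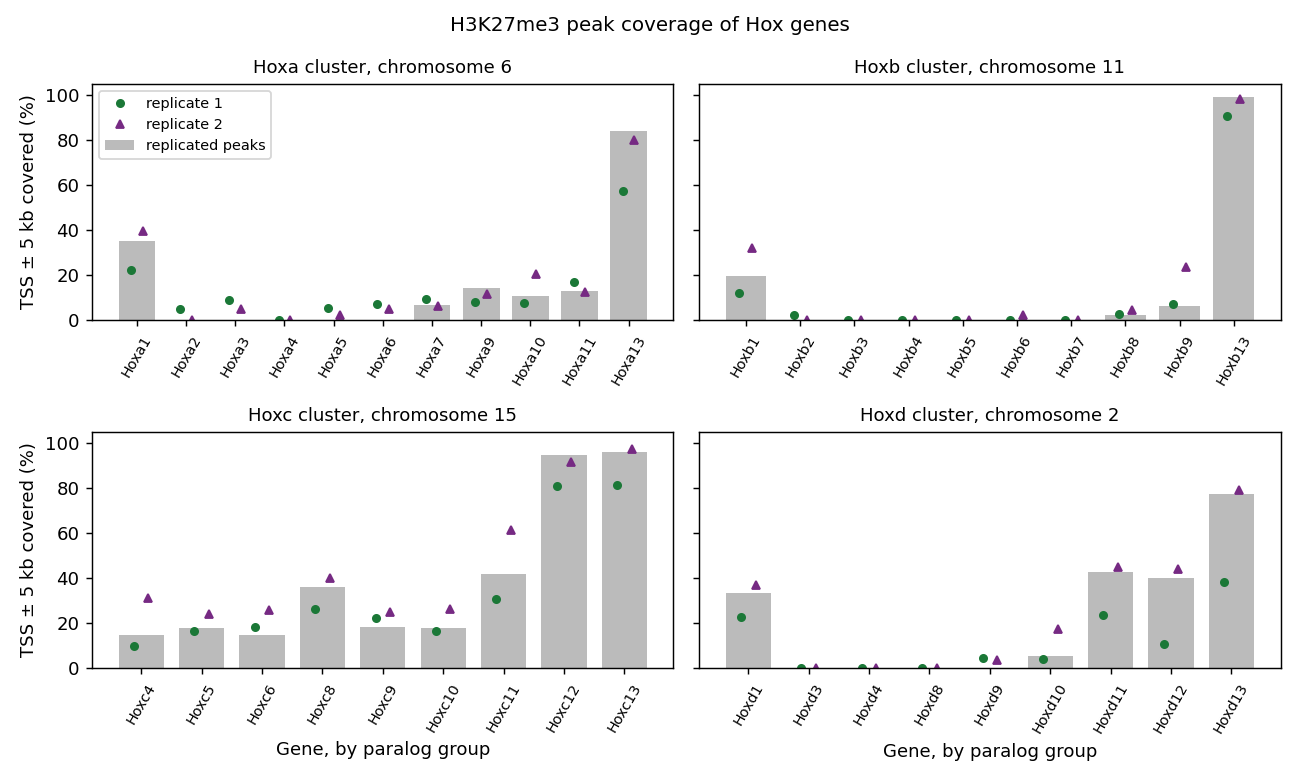
Share of the 5 kb on either side of each Hox start site covered by H3K27me3 peaks, in percent, with genes ordered by paralog group in each of the clusters. Grey bars are replicated peaks, and circles and triangles are the peaks of replicates 1 and 2 called alone. Coverage by replicated peaks is 77.3% or more at the group 13 genes, while replicate 1 alone covers 38.1% at Hoxd13 and 57.3% at Hoxa13.

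Of the 10 longest domains, all but 1 contained the start of at least 1 transcription factor gene. Merging replicated peaks no more than 3 kb apart gave 8417 domains, of which 545 were at least 10 kb long. The longest, 102.8 kb on chromosome 1 (78118437 to 78221253, mm10), contained the start of Pax3, a neural crest and muscle regulator. Next were domains at Dmbx1 (90.7 kb), Nfix (78.5 kb), Zic1 and Zic4 (78.3 kb), Tlx1 (75.6 kb), Tbx5 (73.5 kb), Nkx2-3 (61.4 kb), Pax7 (59.1 kb) and Hoxc11 to Hoxc13 (58.1 kb). A 65.1 kb domain on chromosome 7 held no protein-coding start and contained the host gene of the microRNA Mir9-3. Of the broad domains, 386 (70.8%) contained a protein-coding start, for 454 genes in all. These included 106 of the 199 genes in the transcription factor lists. The number of broad domains was 1087 in replicate 2 alone, 688 in replicate 1 alone and 326 with a −log10 q of at least 5.

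Replicated peaks were concentrated in promoters and exons. For this comparison, promoters were the 1 kb on either side of every protein-coding transcript start, and exons were counted outside them. Promoters held 23.0% of peak bases, against 2.62% ± 0.23 (SD) in 200 rotations, an 8.80-fold difference, and exons held 8.60% against 3.23%. Introns held 29.3% against 35.7%, and intergenic sequence held 39.1% against 58.5%. Each share lay outside the range of all rotations (two-sided permutation p = 0.00995, the smallest these rotations can give).

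The X chromosome was where the replicates differed most. Replicate 1 had 1237 X peaks and replicate 2 had 8050, a 6.51-fold difference, while the 19 autosomes differed by 0.988-fold to 1.16-fold. In bases, X peaks covered 329 kb in replicate 1 and 2334 kb in replicate 2. In the replicated list, 85 of 948 X promoters (8.97%) and 2901 of 20780 autosomal promoters (14.0%) were marked, an odds ratio of 0.607 (two-sided Fisher's exact test, p = 5.42e-06). The direction was opposite between the replicates. X promoters were marked less often than autosomal ones in replicate 1 (104 of 948 against 3912 of 20780, Fisher's exact test, odds ratio 0.531, p = 1.48e-10) and more often in replicate 2 (219 of 948 against 3659 of 20780, odds ratio 1.41, p = 3.01e-05). With a −log10 q of at least 5 the odds ratio was 0.282, with 25% of the promoter covered 0.351, and with pooled peaks 0.832 (Fisher's exact test, p = 0.0474). The replicates give no common direction for X promoters. Kappa between replicates was 0.414 on X and 0.728 on autosomes. Cited1, a nephron progenitor gene on X, was marked with 15.0% coverage.

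**Figure D3:**
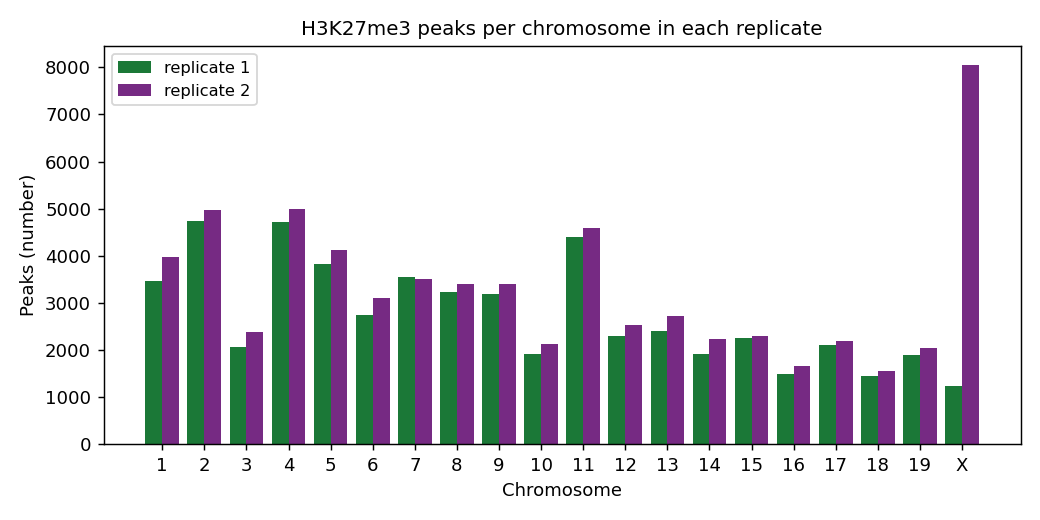
Number of H3K27me3 peaks called in each replicate alone, by chromosome. The pairs of bars are similar on the 19 autosomes, and on X the bars stand at 1237 in replicate 1 and 8050 in replicate 2.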

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

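The set of peaks overlapping both replicates and the autosome-only values were chosen after seeing the data. Of the main results under alternatives, 67 kept their direction and side of the threshold or their size. Another 16 changed in size, 2 reversed direction and 3 came to pass the threshold. With a −log10 q of at least 5 the signal correlation was 0.410, kappa 0.679, marked promoters 1983, replicated peaks 8524 and broad domains 326. With 25% of the promoter covered kappa was 0.813, with a 2.5 kb window 0.686 and on autosomes 0.728. Pooled peaks numbered 45344, with 856 broad domains and a Hox group 9 to 11 difference of 14.4 points. Merge distances of 1 and 10 kb gave 349 and 990 domains. Among CpG-rich promoters alone 2 lists had fewer marked promoters, where fewer list members were tested. A CpG ratio of 0.75 gave an odds ratio of 1.00 for CpG-rich promoters. With 1 replicate's list at a time, the X odds ratio ranged from 0.531 (replicate 1) to 1.41 (replicate 2, reversed), the Hox group 9 to 11 difference from 6.76 to 13.5 points, peaks from 54867 to 65849 and broad domains from 688 to 1087. Polycomb subunit genes, not called in any setting, were marked at 20.0%, above other genes, with any transcript's start, with pooled peaks and in replicate 2 alone, and at 16.0% in replicate 1 alone. Apart from these 3, the single lists gave 334 same calls, 15 lost and 7 gained of 359, and the named genes kept their call in 867 of 880. The causes were not tested, except that stricter thresholds and merge distances change counts by construction. No paired analysis was possible because there is 1 group. Depth is unknown and its effect could not be measured.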

Other observations

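Tests chosen only after the result was seen are those of gene families by symbol, of the X ratio over all peaks and at −log10 q of 2, 3 and 4, and of the rRNA locus. Also chosen then were those of the difference in coverage between lineage transcription factors, of their marked shares and of the share of that difference tied to the CpG ratio.

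Several gene families outside the fixed lists had more or fewer marked promoters than other genes; those named here were picked after the values were seen. Genes were grouped by the letters that begin their symbols, with members of the fixed lists left out. The counts below therefore need not cover every gene of a family. This gave 627 families of at least 5 genes, each compared with all other genes by Fisher's exact test with Benjamini-Hochberg adjustment. In 30 families more promoters were marked and in 8 fewer. The latter included Olfr genes (0 of 42) that the fixed olfactory receptor list had not taken in. All 8 Grm genes, for metabotropic glutamate receptors, were marked (Fisher's exact test, adjusted p = 1.98e-05), as were 13 of 16 Syt genes, for synaptotagmins (adjusted p = 7.12e-07), 10 of 14 Htr genes, for serotonin receptors (adjusted p = 0.000175), and all 8 Kcnh potassium channel genes. All 6 Dlx genes and all 5 Zic genes, both of developmental transcription factors, and all 5 Sstr somatostatin receptor genes were marked. The called families also included 6 of 7 Alox lipoxygenase genes, 14 of 41 Col collagen genes and 74 of 355 Slc solute carrier genes. Zfp zinc finger genes were marked at 12 of 393 promoters (Fisher's exact test, adjusted p = 4.57e-10), histone genes at 0 of 67 and Mrpl mitochondrial ribosomal protein genes at 0 of 49. Members of a family can lie side by side, so their calls are not independent.

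Replicate 2 had 6.51 times as many X peaks as replicate 1, above the highest autosomal ratio of 1.16. Autosomal peaks also covered 1.35 times as many bases in replicate 2. The comparison restates the pattern, so it is no separate test of a library-wide difference in depth or calling. Most X peaks of replicate 2 were weak (median −log10 q 1.71, against 2.31 on autosomes), as were those of replicate 1 (1.43, against 1.86). The X ratio still stayed above the autosomal ratios at stricter thresholds. It was 15.4 with a −log10 q of at least 2 (3701 against 241 peaks, autosomes at most 1.88). With at least 3 it was 8.71 (autosomes at most 1.61), and with at least 4 it was 20.5 (autosomes at most 2.03). With at least 5 it was 21.1 (274 against 13, autosomes at most 2.27). This argues against peaks near the threshold as the whole cause. Of 7551 X peaks of replicate 2 without a replicate 1 overlap, 57.9% lay within 5 kb of a gene body. This was 1.89 times the mean of rotated peaks, against at most 1.45 on autosomes. Rotations on X gave 30.6% on average but up to 50.9%, and the ratio depends on each chromosome's own mean. The comparison therefore cannot decide on an even rise of X dosage over the control. A candidate explanation is a larger share of female embryos, and so of inactive X chromosomes, in the replicate 2 pool, but the test written for it gave no support: 4 of 8 genes known to escape inactivation had a replicate 2 peak within 5 kb, against 434 of 940 other X genes (Fisher's exact p = 1.0). With 8 genes this hypothesis stays open, as does any difference between the replicates' X that the labels do not record.

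A second pattern is an annotated rRNA gene on chromosome 17 among the strongest pooled peaks by q-value. Its 2 peaks (39843005 to 39846797 and 39847856 to 39848923) ranked 1 and 3, yet their signal values, 2.78 at most, lay below the pooled median of 3.17. This may reflect multi-copy ribosomal sequence collapsed to a single place in the assembly, which would give many reads in sample and control alike. No biological explanation was tested. The peak ranked second, inside Cdk8 on chromosome 5, had a signal value of 7.06, so low signal did not hold for all of the top peaks.

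The last pattern concerns transcription factor genes of the kidney lineages, chosen after values in the fixed lists had been seen, so that its p-values restate the pattern and do not test it. Of these genes 23 of 32 were marked, against 51 of 54 of neuronal, muscle, heart and gut lineages (Fisher's exact p = 0.00744), and the marked ones had a mean coverage of 58.0% ± 29.6 (SD) against 85.7% ± 19.2 (permutation p = 1.00e-05, the smallest these permutations can give). The difference was -27.7 points in the replicated list, -27.5 in replicate 1 alone and -26.7 in replicate 2 alone. The liver, gonad and adrenal, blood and immune, and endothelial lists were not drawn on, so other lineages in general are not covered. The mean CpG ratio was not lower in the kidney genes (0.675 against 0.656), and after a linear fit on it the difference was -28.5 points (permutation p = 1.00e-05), so adjustment widened it by 0.843 (bootstrap 95% interval -3.90 to 4.03, where a negative value is a narrowing), which argues against lower CpG content as the cause. Activity of these genes, free of the mark, in part of the cells of the mixed tissue stays an untested hypothesis, since expression was not measured here, as do other differences between the gene sets.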
